A study of Mus musculus with 2 samples.

How the data were processed

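The data are a 5hmC-Seal profile of mouse prospermatogonia, the male germ cells of the foetal testis, at embryonic day 17.5. 5-hydroxymethylcytosine (5hmC) is the oxidised form of 5-methylcytosine made by TET enzymes. In 5hmC-Seal a modified glucose is attached to 5hmC, biotin is added to it, and the tagged DNA fragments are captured on streptavidin. Per the labels' protocols and the design text, 30000 frozen wild-type cells from several embryos were pooled, and 50 ng of sheared DNA entered the capture. The samples are 1 captured library and 1 library of the DNA before capture, both from batch 1. Only the captured library has a file that was used here, a list of broad peaks.

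Per the submitters' processing notes, the tools named are Trim Galore, Bowtie2 2.5.0, SAMtools 1.16.1, bedtools 2.27.1, MACS2 2.1.0 and deepTools 3.5.1, with mouse build mm10. The roles and order of these tools, the peak caller's settings, the handling of reads that map to several places and the use of the library before capture as a control are not given in the sources used here. The authors' deposited list gives each peak a fold enrichment, which is a ratio of the captured signal to the background the caller assumed. The deposited list also gives a −log10 p and a −log10 q for each peak, and these are the caller's values for the whole broad peak. The deposited score was the whole part of 10 times the −log10 q in 108385 of the 108395 peaks. The lowest −log10 q was 1.01, so the list reaches q values near 0.0976 and holds weak calls. Peaks were numbered without gaps, and 0 neighbouring peaks overlapped.

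The file holds no read counts, so the depth is unknown, and no interval here covers the error of a peak's fold. The captured library has no replicate. No test across samples was therefore possible, and every value describes this library and its peak calls. Exact Clopper-Pearson 95% intervals are given for shares of peaks or genes, and exact Poisson 95% intervals for peaks per Mb; they cover counting error only. Neighbouring peaks and genes are not independent of each other.

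Genes came from a table of assembly GRCm38.p6, the same build as mm10. It holds gene spans, symbols and gene types, and gives no strand, exon or sequence. Of its 49997 genes, 49603 on chromosomes 1 to 19, X and Y were used. Another 340 genes were left out because they start in the opening 3 Mb gap of a chromosome other than Y, so their positions are those of scaffolds. Since the transcription start could not be placed, the promoter planned for the tests was replaced by windows of 1 kb on each side of both ends of a gene, called gene ends. A gene body was the span of a gene of 5 kb or more without 1 kb at each end. The split into exons and introns, CpG content, promoter classes and matching on base composition were not run.

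Peak midpoints were assigned to gene ends, else to the inside of genes, else to the outside. Shares were compared with 1000 random placements of the same widths on the same chromosome, between the first and last peak or gene; internal assembly gaps were not excluded. A gene had a gene-end peak when a peak overlapped a window by at least 1 bp, and a peak near several genes counted for each of them. Such a peak could lie wholly outside the gene, as for Henmt1, Inpp5f, Phlda2, Vmn1r88 and Vmn1r238, among others. For each gene list, the share of its protein-coding members with such a peak was placed among 10000 random lists of equal size, matched on 10 classes of gene length. Random lists were drawn from all protein-coding genes, members of the list included. The median share of the gene body covered was treated in the same way. A percentile above 97.5 or below 2.5 was taken as outside the random range. Random lists tied with the list were split evenly between above and below it. The percentile describes this library, and no allowance was made for the number of lists. The lists were germ cell identity, piRNA pathway, meiosis, spermiogenesis, imprinted genes, DNA methylation machinery, pluripotency, Hox clusters, other developmental transcription factors, gonadal soma, blood and endothelium, ribosomal and housekeeping genes, olfactory receptors, vomeronasal receptors, genes with a Zfp symbol and a short list of named genes. All list symbols were found, 5 of them as synonyms.

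The tests, the alternatives, the gene lists and the rule for naming genes were fixed before the data were examined. The rule names the short list, with or without peaks; the 3 members of each other list with the highest gene-end fold; the 10 protein-coding genes with the highest gene-end fold; the 10 with the largest body share covered; and the 5 highest and 5 widest peaks. The alternatives were peaks with −log10 q of at least 3 or 5, peaks within 1 kb merged, any overlap in place of the midpoint, protein-coding genes only, a gene-end window of 250 bp, genes of 20 kb or more, no matching on length, and other definitions of strong peaks. Leaving out X and Y, moving a list along the genome and keeping 1 gene per run of members within 100 kb were added after the data were seen. The difference between the spermiogenesis and meiosis lists was not among the tests fixed beforehand.

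Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The code was tested on simulated data. For gene ends, 20000 placed peaks with 10% of them moved to gene ends gave a recovered fold of 2.47 against 2.47 built in, and 1.01 with no effect. For lists at gene ends, 200 random lists of 40 genes among 21779 protein-coding genes fell outside the random range in 5% of cases with no effect. With a share raised from 25% to 50%, 90% of lists passed the upper limit. The simulated genes had peaks independently of their length and neighbours. These rates therefore need not hold for real lists, whose members can be neighbours and share peaks.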

Results

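The series asks how TET1, an enzyme that oxidises 5-methylcytosine, and its activity outside catalysis relate to new DNA methylation in the male germline. The samples used here are wild type. They are 1 captured 5hmC library and 1 library before capture from prospermatogonia at E17.5 of embryonic development, a stage at which the male germline is gaining DNA methylation. The comparisons are therefore within the captured library, between chromosomes, genomic positions and groups of genes. The depth is unknown, there is no replicate, and the fold enrichment and q of each peak are the authors' values.

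5hmC enrichment was called at 108395 peaks, which covered 97.0 Mb or 3.65% of the genome span. Most peaks were narrow and weak. The median width was 636 bp and the median fold enrichment 3.35, and 90% of the peaks had a fold of at most 5.43. Only 590 peaks were wider than 5 kb and 171 had a fold over 10. At a −log10 q of 5 or more, 12931 peaks and 17.9 Mb were left, so the size of the peak set follows the threshold of the caller.

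The X chromosome carried far fewer peaks than any autosome. It had 11.7 peaks per Mb (95% Poisson interval 11.2 to 12.3), against an autosomal median of 44.2 and an autosomal range from 35.1 on chromosome 14 to 57.1 on chromosome 11. The Y chromosome had 4.34 peaks per Mb (3.92 to 4.79). Both are present as 1 copy in male cells. For the Y, neither copy number nor reads that map to several places was tested as a cause of the low density. The peaks called on the X had a median fold of 3.82, above the autosomal median of 3.34. Among the 19 autosomes, peak density followed gene density, with a Spearman rho of 0.805 between peaks and protein-coding genes per Mb. Across 2375 autosomal windows of 1 Mb the rho was 0.675. These correlations are across regions of 1 library, and regions are not independent replicates.

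**Figure D1:**
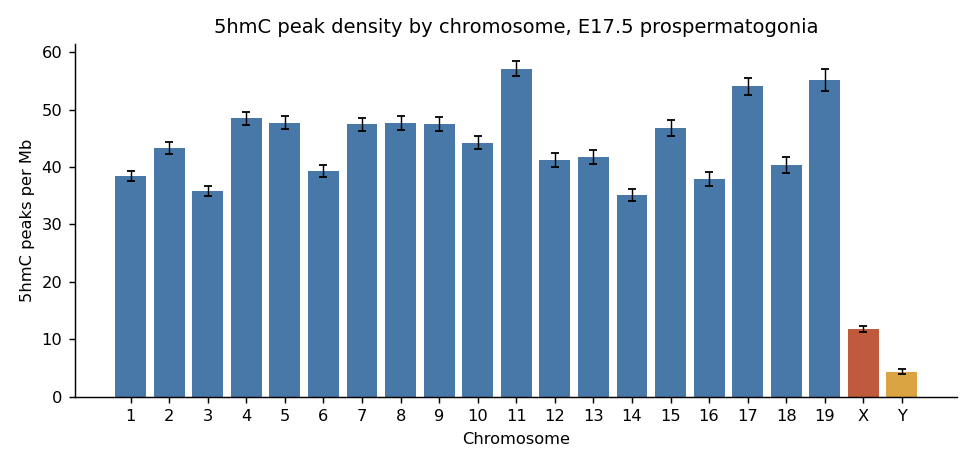
Peaks of 5hmC per Mb (vertical axis) for each chromosome (horizontal axis) in the captured library; bars are densities and error lines exact 95% Poisson intervals for counting error. Chromosomes 1 to 19 lie between 35.1 and 57.1 peaks per Mb, X at 11.7 and Y at 4.34.

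Most peaks lay in genes. Gene interiors held 54.4% of peak midpoints, against 45.2% in the random placements, a 1.20-fold excess (1.19 to 1.22 over the placements). Gene ends held 8.46% of midpoints against 6.42% by placement, 1.32-fold (1.27 to 1.36). Sequence outside genes held 37.1% against 48.3%, 0.769-fold (0.760 to 0.777). The direction turned at a stricter threshold. At a −log10 q of 5 or more, gene ends were at 0.782-fold, gene interiors at 0.617-fold and sequence outside genes at 1.38-fold.

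The strongest peaks lay mostly outside genes. Of the 10840 peaks in the top 10% by fold enrichment, 68.3% (exact 95% interval 67.5 to 69.2) had their midpoint outside genes, against 33.7% (33.4 to 34.0) of the other 97555 peaks. Gene interiors held 26.9% (26.02 to 27.70) of the strong peaks and 57.5% (57.1 to 57.8) of the others. Gene ends held 4.80% (4.40 to 5.22) and 8.87% (8.69 to 9.05). Strong peaks were also wider, with a median of 848 bp against 606 bp. Ranking by q in place of fold gave 68.2% outside genes.

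**Figure D2:**
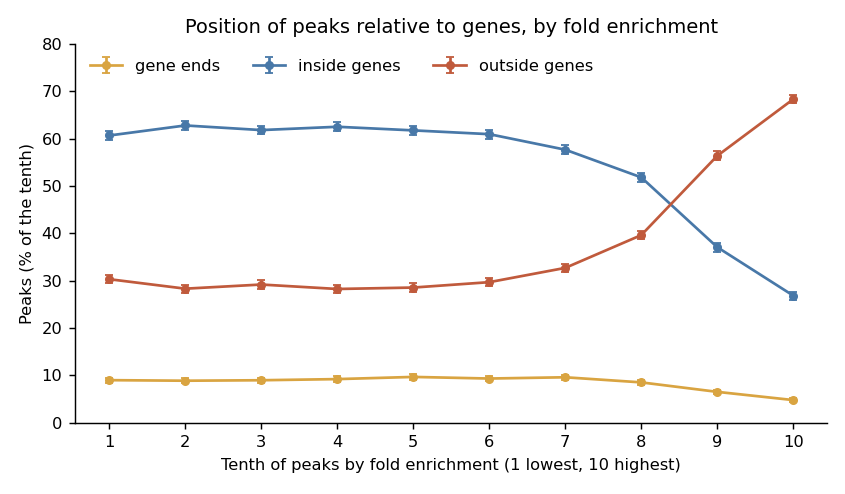
Percentage of peaks (vertical axis) at gene ends, inside genes and outside genes in 10 equal classes of fold enrichment (horizontal axis, lowest to highest), with exact 95% intervals for counting error. The share outside genes is 30.3% in the lowest class, 28.6% in class 5, 56.4% in class 9 and 68.3% in class 10.

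Of the 5 peaks with the highest fold, 2 lay on genes of small non-coding RNAs. The highest, at fold 22.7, covered chromosome 9 from 78175328 to 78175633, within Rn7sk, the gene of the 7SK RNA that regulates transcription elongation. A peak of fold 16.3 on chromosome 14, from 50807448 to 50807770, lay on Rpph1, the gene of the RNA of RNase P. Between them stood a peak of fold 20.3 on chromosome 10 from 47804436 to 47804705, 1289 kb from the nearest protein-coding gene Grik2. A peak of fold 18.0 lay in Tiam2 on chromosome 17, from 3352508 to 3353453. A peak of fold 16.5 lay on chromosome 12 from 61970340 to 61971096, 112 kb from Lrfn5. The widest peak, 38.3 kb, spanned chromosome 9 from 3000008 to 3038270 at the centromeric start of the assembled sequence, 297 kb from the nearest protein-coding gene Alkbh8. Its −log10 q was 594 at a fold of 5.24, and reads from repeated sequence could not be checked there. The next 3 by width were 18.5 kb near Zfp954 and 14.3 kb near Olfr1350 on chromosome 7, and 17.46 kb near D10Wsu102e on chromosome 10. The fifth, 12.9 kb, lay in Cdh3, a cadherin gene on chromosome 8.

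Among protein-coding genes, 26.6% (5785 of 21779; exact 95% interval 25.98 to 27.15) had a peak within 1 kb of either end. In 16802 genes of 5 kb or more, 72.4% (71.7 to 73.1) had a peak in the gene body, and the median body share covered was 3.65%. A body share over 50% was found in 179 genes. The 10 highest gene-end folds included those of the ribosomal protein genes Rpsa (12.2) and Rpl8 (10.1). They also included the elongation factor gene Eef1a1 (10.3) and Rpn1 (10.2), a subunit gene of the oligosaccharyltransferase. Parp2 (16.3) and Ccdc107 (13.1) owed their values to peaks on the neighbouring Rpph1 and Rmrp, genes of the RNAs of RNase P and RNase MRP. The other 4 of the top 10 were Gm52481 on the Y (12.6), Zfp991 (12.4), the vomeronasal receptor gene Vmn2r29 (11.3) and Gm40469 (10.3). Body coverage was complete in the elongation factor gene Eef2, in Asmt, whose enzyme makes melatonin and which lies at the end of the X, and in the interleukin receptor gene Il3ra. It was 98.2% in Klhl17, 94.8% in Igsf8, 94.4% in Cxxc1, which encodes a CpG-binding protein, 94.3% in the water channel gene Aqp3, 91.4% in the calmodulin gene Calm3, 88.6% in the chaperone gene Hsp90ab1 and 87.4% in Lynx1.

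Genes of later sperm formation had gene-end peaks more often than length-matched genes, a call lost at a −log10 q of 5 or more. The low share of meiotic genes depended on more settings. In the spermiogenesis list, 17 of 36 genes (47.2%; exact 95% interval 30.4 to 64.5) had a peak, against 23.8% in the random lists, percentile 99.9. The highest folds were 7.77 at Catsper3, a sperm calcium channel gene, 5.13 at Spem1 and 3.81 at Odf1, of the outer dense fibres of the tail. Neighbouring members could share a peak, as the protamine genes Prm2 and Prm3, singled out after their values were seen, did (fold 3.05); with 1 gene kept per run of members within 100 kb, 14 of 32 genes had a peak, percentile 98.65. In the meiosis list, 6 of 42 genes (14.3%; 5.43 to 28.5) had a peak, against 27.6%, percentile 2.19. That share equalled the lower end of the central 95% of random lists, so the call rests on how ties were counted. The meiotic genes with a peak included Iho1 at 3.72, needed for meiotic DNA breaks, Rec8 at 3.46, a meiotic cohesin gene, and Hfm1 at 3.01. The difference between both lists, a contrast not among the tests fixed beforehand, was 32.9 percentage points. Of 10000 pairs of random lists, 2 reached it, and their central 95% ran from -23.8 to 15.5. Such pairs do not allow for the choice of a high and a low list, so they add no separate support. At a −log10 q of 5 or more the difference was 2.78 points, inside the random range (percentile 85.3). Meiotic gene bodies were also little covered, with a median of 1.11%, percentile 0.39, against 2.46% and percentile 34.8 for spermiogenesis. At a −log10 q of 5 or more neither list was outside the random range at gene ends, with 2.78% and 0% of genes. For spermiogenesis the random mean was 1.19% and the range ran to 5.56%, so only a larger excess could have been called. For meiosis 0% is the lowest possible value and the random range began at 0%, so a low share could not be called there. The meiosis list was inside the random range with a window of 250 bp (percentile 4.68) and when moved along the genome (percentile 3.12).

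The piRNA pathway, which silences transposons in these cells, had gene-end peaks at 11 of 24 genes (45.8%; 25.6 to 67.2), against 26.7% in random lists, percentile 97.8. That share equalled the upper end of the central 95% of random lists, so the call rests on how ties were counted. The highest folds in the pathway were 6.60 at Mael, 5.45 at Henmt1 and 4.69 at Spocd1. Piwil4, the nuclear Piwi protein gene of prospermatogonia, had 3.39. The list fell inside the random range with a window of 250 bp (25%, percentile 95.1) and without X and Y (percentile 96.9). Pluripotency genes had peaks at 12 of 25 (48.0%; 27.8 to 68.7), percentile 97.49, just within the random range. The list was above that range with a window of 250 bp (32% against 14.9%, percentile 98.4) and when moved along the genome (98.5). At a −log10 q of 5 or more it was inside (0%, percentile 34.9). Pluripotency genes with a peak included Tcl1 at 4.66, Nanog at 3.89, Zfp42 at 3.84 and Pou5f1, the gene of OCT4, at 3.59. Germ cell identity genes had peaks at 13 of 34 (38.2%; 22.2 to 56.4), percentile 92.1, led by the transcription factor genes Sall4 (4.53), Tfap2c (3.76) and Prdm14 (3.73). The body of Sall4 was 59.9% covered.

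Developmental transcription factors outside the Hox clusters had a low share at their ends that did not hold under every setting. At gene ends, Hox clusters were inside the random range at every planned setting. At a −log10 q of 5 or more they were at 0%, where the random range also began, so a low share could not be called. Among other developmental transcription factors 12 of 67 (17.9%; 9.61 to 29.2) had a peak, against 30.4%, percentile 1.02. This list was inside the random range with a window of 250 bp (percentile 6.39), when moved along the genome (5.47) and with 1 gene per 100 kb run (2.75). At a −log10 q of 5 or more it was at 0% (percentile 17.9). The random range also began at 0% there, so a low share could not be called. Hand1 (3.90), Nkx6-2 (3.72) and Gata3 (3.58) had the highest folds. In the Hox clusters 7 of 39 genes (17.9%; 7.54 to 33.5) had a peak, percentile 3.93, which is inside the random range. The percentile was 21.01 when the list was moved along the genome and 2.005, outside the range, without X and Y. The Hox genes with the highest folds were Hoxb7 (4.09), Hoxa11 (3.92) and Hoxc4 (3.32).

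Large receptor families had few peaks. Of 32 olfactory and 14 vomeronasal receptor genes with a gene-end peak, 6 and 7 had one at a −log10 q of 5 or more. A gene-end peak was found at 2.89% (1.98 to 4.05) of 1109 olfactory receptor genes and 3.98% (2.19 to 6.58) of 352 vomeronasal receptor genes, against 11.5% and 17.0% in random lists, both at percentile 0. At a −log10 q of 5 or more both were inside the random range. Olfactory receptors were at 0.541% against 0.821% (percentile 10.4). Vomeronasal receptors turned above the random mean, at 1.99% against 0.96% (percentile 96.6). The random lists could themselves hold receptor genes. The shortest length class, 144 to 1561 bp, has only 2178 protein-coding genes, 8.03% of them with a gene-end peak. The calls inside the range thus set these families partly against themselves. The highest folds were 8.29 at Olfr212, 8.17 at Olfr53 and 6.79 at Olfr784, and 11.3 at Vmn2r29, 8.52 at Vmn1r88 and 7.37 at Vmn1r238. Genes with a Zfp symbol, mostly zinc-finger genes, had peaks at 24.0% (19.9 to 28.5) of 400, against 29.5%, percentile 0.69. This did not hold when the list was moved along the genome (percentile 20.1), and at a −log10 q of 5 or more the share was above the random mean, 2.5% against 1.33% (percentile 97.3, within the random range). Zfp992 had 9.14 and Zfp27 had 6.65.

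Markers of other cells of the testis lay near the middle of the random range. Gonadal soma genes had peaks at 6 of 26 (23.1%; 8.97 to 43.6), percentile 27.0, with Lhcgr at 4.82, Gata4 at 3.36 and Cyp11a1 at 3.22. Blood and endothelial genes had peaks at 4 of 20 (20%; 5.73 to 43.7), percentile 38.3, with Tie1 at 4.23, Spi1 at 4.20 and Cd68 at 3.55. Ribosomal and housekeeping genes had peaks at 22 of 54 (40.7%; 27.6 to 55.0), percentile 94.1. At a −log10 q of 5 or more they were at 9.26% against 1.57%, percentile 99.9. The tubulin gene Tubb5 had 8.51.

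**Figure D3:**
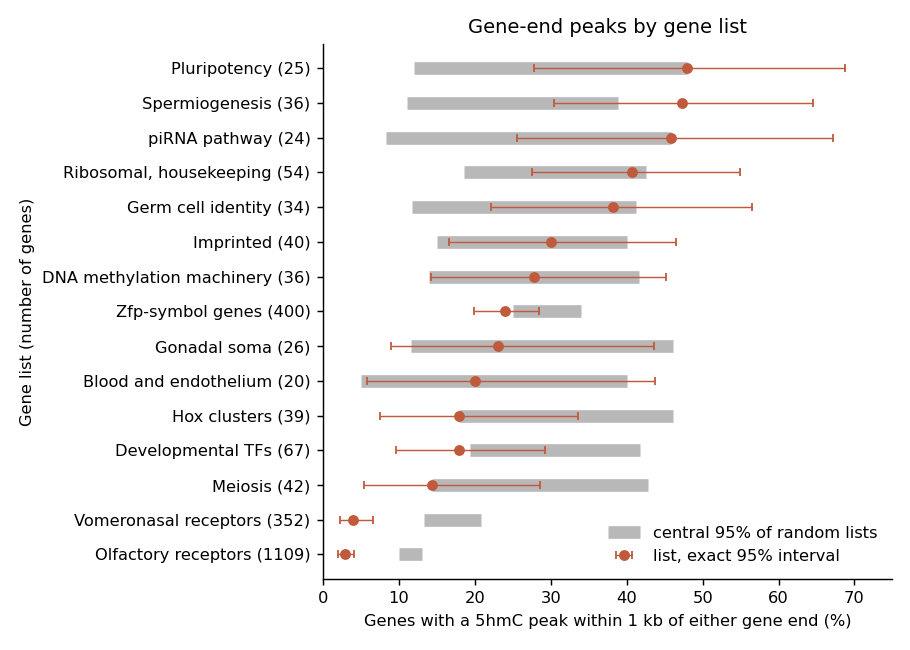
Percentage of protein-coding genes with a 5hmC peak within 1 kb of either gene end (horizontal axis) for each gene list (vertical axis, with the number of genes). Points are lists with exact 95% intervals for counting error and grey bars the central 95% of 10000 length-matched random lists. Spermiogenesis (47.2%) lies above its grey bar, and olfactory (2.89%) and vomeronasal (3.98%) receptors lie far below theirs.

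Imprinted genes had gene-end peaks at 12 of 40 protein-coding members (30%; 16.6 to 46.5), percentile 68.3. Imprint control regions were not annotated here, so no peak was placed relative to them. The highest was 8.91 at Igf2, a growth factor gene, from a peak on chromosome 7 at 142667470 to 142670688. That peak begins past the annotated span of Igf2 (142650768 to 142666816) and overlaps Igf2os, a non-coding gene. H19, a non-coding RNA gene in the same cluster (142575530 to 142578146), had a peak of 4.29 that covered 63.7% of its span. Other values were 4.65 at Inpp5f, 4.44 at Phlda2, 3.61 at Igf2r, 3.49 at Peg3 and 3.12 at Meg3. Snrpn, Kcnq1ot1 and Rasgrf1 had no gene-end peak, and 0.95%, 5.23% and 1.14% of their bodies were covered.

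**Figure D4:**
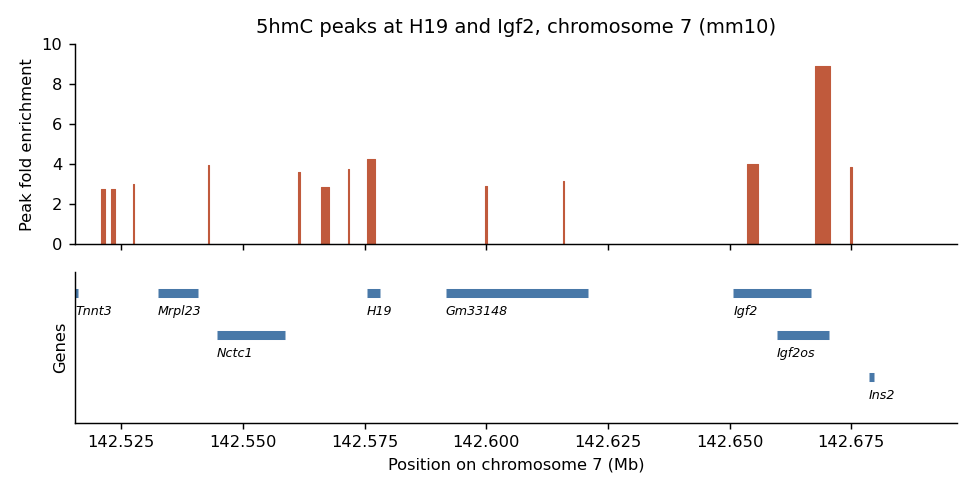
Fold enrichment (vertical axis, upper panel) of 5hmC peaks, drawn at their width, from 142515530 to 142696816 on chromosome 7 of mm10 (horizontal axis, Mb), with annotated gene spans other than microRNA genes in the lower panel. The highest of the 13 peaks, at fold 8.91, lies beside Igf2, and the peak on H19 has a fold of 4.29.

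The DNA methylation machinery was near the random mean, with 10 of 36 genes (27.8%; 14.2 to 45.2), percentile 53.0. Mbd1, which encodes a methyl-CpG-binding protein, had 5.60, and Zfp445, which maintains imprints, 4.48, both from peaks outside the gene span. Tet3 had 4.27. Tet1 had no gene-end peak, and its body was 9.65% covered by 10 peaks in the gene. Dnmt3a, a de novo methyltransferase gene, likewise had no gene-end peak, with 14.8% of its body covered and 21 peaks in the gene. Dnmt3l, its cofactor in germ cells, had 3.04 at a gene end, and Dnmt3c (Dnmt3b-ps1 in the table) had none, with 11.9% of its body covered. In the short list of named genes, 6 of 14 protein-coding members (42.9%; 17.7 to 71.1) had a gene-end peak, percentile 92.7. Stra8, the inducer of meiosis, had 2.90. The germ cell genes Ddx4 and Nanos2 had no gene-end peak. Dazl and Sycp3, also germ cell genes, and Xist had no peak at their ends or in their bodies.

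In gene bodies, the median share covered was outside the random range for 3 lists, all of them low: meiosis, vomeronasal receptors (0%, percentile 0) and Zfp-symbol genes (2.79%, percentile 0.775). The call for Zfp-symbol genes ended without length matching (percentile 3.51) and when the list was moved along the genome (12.5). At a −log10 q of 5 or more the medians of all 3 lists and of their random lists were 0%. The other medians were 9.62% for pluripotency (percentile 95.6), 5.75% for imprinted genes (91.8), 5.16% for germ cell identity (82.6), 5.52% for the piRNA pathway (79.6), 4.45% for the DNA methylation machinery (60.0), 3.95% for the short list of named genes (49.98), 2.93% for developmental transcription factors (39.3), 3.16% for blood and endothelium (36.9) and 2.60% for gonadal soma (33.7). Hox clusters, ribosomal and housekeeping genes and olfactory receptors had a median of 0%, at percentiles 14.7, 16.8 and 14.2.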

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

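The alternatives that move a list along the genome, leave out X and Y, or keep 1 gene per 100 kb run were chosen after the results were seen; the others were planned. The peak threshold had the widest effect. With −log10 q of at least 3 there were 26242 peaks over 30.9 Mb with a median width of 746 bp, and with at least 5 there were 12931 over 17.9 Mb with 858 bp; merging peaks within 1 kb gave 644 bp. The low density of the X held, at 0.236 of the autosomal median by covered kb. With −log10 q of at least 5, placement folds turned to 0.782 at gene ends, 0.617 inside and 1.38 outside genes; the cause was not tested. They kept their direction with any overlap, with protein-coding genes only and without X and Y. In the top 1% by fold, 5.81% of peaks were at gene ends and 25.6% inside genes. Genes with a body peak were 82.8% among genes of 20 kb or more, and 10.8%, with a median body share of 0%, at the stricter q. At gene ends with the 250 bp window, the piRNA pathway (25%), meiosis (4.76%) and developmental transcription factors (8.96%) entered the random range. Pluripotency (32%) left it. With the stricter q, spermiogenesis (2.78%) and olfactory receptors (0.541%) entered it. Ribosomal and housekeeping genes (9.26%) left it. Vomeronasal receptors (1.99%) and Zfp-symbol genes (2.5%) turned above the random mean, inside the range. Meiosis and developmental transcription factors, both at 0%, were also inside the range at the stricter q. Their random ranges began at 0%, the lowest possible value, so a low share could not be called. When moved along the genome, meiosis (14.3%, percentile 3.12), developmental transcription factors (17.9%) and Zfp-symbol genes (24%) entered the range, and pluripotency (48%) and ribosomal and housekeeping genes (40.7%) left it. Without X and Y, the piRNA pathway (45.8%) entered and Hox clusters (17.9%) left it. With 1 gene per run, developmental transcription factors (19.4%) and Zfp-symbol genes (25.6%) entered it, and spermiogenesis did not, with 14 of 32 genes. The difference between spermiogenesis and meiosis at gene ends was inside the range of random pairs at the stricter q (2.78 points), and outside it under the other 4 alternatives run (29.5 to 34.1 points). For gene bodies, the stricter q gave a median of 0% for meiosis, vomeronasal receptors and Zfp-symbol genes, equal to random lists. Without length matching, Hox clusters, ribosomal and housekeeping genes and olfactory receptors, all 0%, left the range and Zfp-symbol genes (2.79%) entered it; moved along the genome, ribosomal and housekeeping genes and olfactory receptors (0%) left it and Zfp-symbol genes (2.79%) entered it. The causes of these changes were not tested. Of 68 named genes with a gene-end peak, 39 had one with the 250 bp window, of which 36 kept their fold, and 27 had one at the stricter q, with the fold kept. CpG content, promoter classes, placement matched on base composition, the asymmetric promoter and matching on CpG density were not run, since they need sequence or strand, and matching on gene length was already the main choice. The depth is unknown, so a gene without a peak cannot be read as a gene without 5hmC.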

Other observations

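The tests of the shared background on the X and of the peaks on genes of non-coding RNAs, and the gene families below, were chosen after the results were seen. The tests of gene density, of windows of tandem copies and of width were set before their values were seen.

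Protein-coding genes were also grouped into 100 families by the start of their symbol, each with at least 20 genes and compared with 2000 length-matched random lists. At gene ends 14 families lay above the random range and 17 below it, where chance gives 2.5 on each side. The highest were the Dusp phosphatase genes (15 of 24; 62.5%), the Krt keratin genes (32 of 53; 60.4%), the Snx sorting nexins (17 of 30; 56.7%) and the Polr polymerase subunits (15 of 28; 53.6%). Those below the range included the Lce genes of the skin barrier (0 of 21; exact 95% upper limit 16.1%), Tas taste receptors (1 of 38), Prl prolactins (1 of 26), Mup urinary proteins (1 of 24) and Pramel genes (2 of 47). Members of many of these families lie side by side, so their genes are not independent. Since this many families left the range, leaving it was common among groups of genes. The same limit applies to the calls for the gene lists above.

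By gene type, a gene-end peak was found at 29.8% (exact 95% interval 29.0 to 30.7) of 12639 long non-coding RNA genes and 28.7% (26.2 to 31.4) of 1228 microRNA genes. It was found at 3.72% (2.098 to 6.065) of 403 tRNA genes and 1.87% (0.756 to 3.82) of 374 immune receptor V segments. The peaks with the highest −log10 q were not those with the highest fold. The highest, 9128, was on chromosome 2 from 98666246 to 98667323 at a fold of 3.79, 1035 kb from the nearest protein-coding gene Lrrc4c. Another of the highest, 1930, lay close by, from 98662238 to 98662958, at a fold of 3.38. Reads from repeated sequence could not be checked at either peak, so no conclusion was drawn from their q values.

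The X had 0.302 times the peaks of autosomal windows with as many protein-coding genes (95% bootstrap interval 0.267 to 0.340), which argues against lower gene density as the whole cause. A candidate explanation is that the caller held the single-copy X to the background of the autosomes. In 3 fold classes between 3 and 5, the median −log10 p on the X differed by at most 0.997% from the autosomal one; lower and higher folds were not compared. Halved signal would give the X as many peaks at fold 3 or more as the autosomes have at fold 6 or more, 3.02 per Mb, but it had 10.3 (95% Poisson interval 9.78 to 10.8); as the fold of a broad peak is a mean over a span that changes with the signal, this leaves the explanation open. No biological explanation was tested, and a true difference in 5hmC on the X stays open.

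The excess of strong peaks outside genes does not rest on a few windows of tandem copies. With the 26 windows of 1 Mb richest in such peaks left out, 94.5% of the strong peaks outside genes were left, and the share of strong peaks outside genes was 67.4%. Width does not account for it either, since in each of 3 classes of peak width strong peaks were outside genes more often than the others, by at least 29.7 percentage points. Young repeats, reads placed in several copies and base composition could each play a part and were not tested here, for want of sequence and repeat annotation. No biological explanation was tested.

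Several of the highest peaks lay on genes of abundant non-coding RNAs. One candidate explanation is reads of the RNA itself, which ends where the gene ends: of the 6 listed genes of 200 to 400 bp under a peak, 3 had both peak ends within 50 bp of the gene ends (Rn7sk, Rpph1 and Rmrp), against 8 of 88 other genes of that length covered over at least 50% of their span. The other 3 were the RNase P RNA-like genes Rprl1, Rprl2 and Rprl3, whose peaks ran past the gene, and 6 genes are too few to decide. RNA carried over in proportion to its abundance should mark most such genes; 52.9% of the 17 listed genes were under a peak, and up to 88.2% if the 6 genes with several copies and no peak lost their reads in mapping, so this cannot be told apart from other causes. Reads shared with copies elsewhere and 5hmC at these genes stay open. The listed genes are all non-coding. The same explanation was not tested for ribosomal and housekeeping genes, which at a −log10 q of 5 or more were at percentile 99.9 at gene ends.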
